A study of Neurospora crassa with 16 samples.

How the data were processed

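The series covers Neurospora crassa wild type and strains lacking set-7, npf, dim-5, dim-3 or set-7 and dim-5, of which Δdim-3 was used for ChIP-seq only. It holds 16 samples in 12 groups: 9 of polyadenylated RNA, 4 of Hi-C and 3 of ChIP-seq. Mycelia were used for the RNA samples except Δdim-5, for which the labels name germinated conidia, and spheroplasts for Hi-C. Comparisons, alternatives and the rule for naming genes were fixed before the data were examined, except for library totals without TMM, thinned wild-type counts, Hi-C contact over the mean between linkage groups, Hi-C without the left end of linkage group V, and shares of background contacts as medians or with 40 kb bins, which were chosen after seeing the main results, as was the naming of 4 examples per symbol list.

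The deposited count files hold raw reads per gene, which the authors made with TopHat, SAMtools and HTSeq by the submitters' processing notes, without versions. The authors' deposited tables of changed genes hold log2 fold changes from DESeq. The same deposited tables hold an adjusted p-value per gene. The deposited observed over expected Hi-C matrices hold the ratio of observed to expected contact by the authors, who did not state how the expected value was computed. The deposited balanced Hi-C matrices hold contact signal per pair of bins after iterative correction by the authors. Per the labels 2 Hi-C replicates were made per strain, and 1 pooled matrix per strain was deposited and used. The wild-type matrix was recomputed by the authors from an earlier experiment. A strand setting for counting was stated for Δdim-5 only. Gene coordinates are those of the authors' annotation (or74a supercontigs 12), with linkage groups I to VII and positions counted from 1. Counts cover 9730 genes, of which 9729 have a row in the reference table and 1118 a symbol of their own. Of the models, 2222 overlap another, and such genes are marked in the text.

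Reads assigned to genes numbered from 7003362 to 21358338 per library, and from 5.71% to 11.3% of reads fell in no gene. Replicates correlated at r = 0.985 to 0.992 on log2 CPM. The 8 libraries of wild type, Δset-7, Δnpf and Δset-7 Δdim-5 were fitted together in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors from 0.852 to 1.13, quasi-likelihood F-test), which left 8216 genes, 4 residual degrees of freedom and a common dispersion of 0.0149. Genes changed at a Benjamini-Hochberg adjusted p under 0.05 in each of 6 comparisons, and a 4-fold change means a log2 of at least 2. SE is the log2 change over the root of F. On simulated data, changes were planted only in genes with at least 5 CPM. Of these, 87 of 100 with a 2-fold change and 100 of 100 with a 4-fold change were found. Among 200 calls, 13 were false. Recovery of genes with lower expression was not simulated. Named genes are the 12 largest rises and 12 largest falls per mutant (5 each between mutants, 10 each for Δdim-5). Members of curated lists and examples of symbol lists are named as well. The largest changes were taken among changed genes with a mean of at least 5 CPM over the 8 libraries. Both libraries of 1 group also had to lie beyond both of the other. For Δdim-5 the smaller difference of the 2 files was ranked, at a mean of at least 5 CPM. Where a group had no read, the fold is a lower bound at 3 reads over the group, and where it had 1 to 3 reads an exact 95% counting interval is given.

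Lists with at least 3 tested members were tested with limma 3.58.1 camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. They were curated lists, lists by gene symbol, and chromosome ends (genes within 100 kb), centromere flanks and interiors. Another 11 lists that needed keywords in gene descriptions were not run. Counts near ends were compared by Fisher's exact test. Overlaps were set beside n1×n2/N and 20 simulations of unchanged groups that share the wild-type libraries. Δdim-5 was compared on plain CPM with a pseudocount of 0.5 and against 10000 random lists, with no test.

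Hi-C matrices of 50 kb bins (813 bins on linkage groups) were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Ends are the outer 100 kb, centromeres the bins over the largest interval without genes, and contact is divided by the matrix mean, or within a linkage group by the mean at the same distance. The share of uniform background was the drop from the wild-type value, divided by the excess of that value over the matrix mean, or solved likewise from values over the matrix median. On simulated matrices the largest error was 3.81%. Alternatives were DESeq2 1.42.0, other scalings and filters, a replicate block, single groups, leaving out each library, ends of 50 kb and 200 kb, 40 kb bins, medians and observed over expected matrices. The 10 kb matrix of Δnpf is truncated and was not used, and the ChIP-seq samples were not analysed here.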

Results

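Gene expression and chromosome contacts were measured in Neurospora crassa, a filamentous fungus with 7 linkage groups, in wild type and in strains lacking genes of heterochromatin formation. The strains lacked set-7, the histone methyltransferase gene of facultative heterochromatin, npf, which encodes a histone-binding protein of the same pathway, dim-5, the histone methyltransferase gene of constitutive heterochromatin, or both set-7 and dim-5. In this series a strain lacking dim-3 was used for ChIP-seq only. The series holds 16 samples, of which 9 are polyadenylated RNA, 4 are Hi-C and 3 are ChIP-seq. The RNA samples are 2 mycelial libraries each of wild type, Δset-7, Δnpf and Δset-7 Δdim-5, and 1 sample of Δdim-5 that came as 2 count files. Hi-C gave 1 contact matrix each for wild type, Δset-7, Δnpf and Δset-7 Δdim-5, and the ChIP-seq samples were not analysed here. Reads assigned to genes numbered 15428984 and 21358338 in the wild-type libraries, 8204284 and 7569184 in Δset-7, 7003362 and 8261074 in Δnpf, 7103667 and 7349516 in Δset-7 Δdim-5, and 7743179 and 7870343 in the Δdim-5 files. The wild-type libraries, which hold more reads and carry longer barcodes than all mutant libraries, may differ from them by library batch, which a comparison with wild type alone does not separate from mutation. The names of the Δset-7 libraries give different strain numbers, and the mating-type gene matA-1 had 0 and 15 reads in them, against 37 and 44 in wild type, 0 and 0 in Δnpf and 12 and 26 in Δset-7 Δdim-5. All expression levels are CPM (reads scaled to library size) as mean ± SD, all changes are log2 fold changes ± SE, and n = 2 libraries per group unless stated. Adjusted p-values of edgeR, here and below, measure the spread between these libraries and not between independent experiments. Those of limma camera set the genes of a list against all other tested genes. Permutation p-values measure the spread over chromosome ends.

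The deleted genes showed whether each library carried its deletion. Reads of set-7 fell 19.6-fold in Δset-7, from 13.1 ± 1.16 to 0.619 ± 0.876 CPM, where 1 library held 11 reads and the other 0 (a log2 change of -10.05 without replicate 1 and -3.39 without replicate 2, in place of -4.29 ± 0.53). They fell 11.6-fold in Δset-7 Δdim-5, to 1.12 ± 0.273 CPM. The npf gene, NCU06679 (listed as cac-3 in the reference), fell 20.0-fold in Δnpf, from 44.0 ± 2.22 to 2.19 ± 0.212 CPM. No read of dim-5 was counted in Δset-7 Δdim-5 or in either Δdim-5 file, against 5.43 ± 0.0891 CPM in wild type, which puts it at least 26.0-fold lower in Δset-7 Δdim-5 at a floor of 3 reads over the group. In Δnpf, set-7 stood at 18.8 ± 2.20 CPM (edgeR adjusted p = 0.186).

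A small set of genes rose strongly in Δset-7 against wild type, and several of the largest rises lay near the right end of linkage group V and the left end of linkage group II. NCU07152, at 6411400 to 6412219 of linkage group V and 28.2 kb from its end, went from 0.0373 ± 0.0528 to 13.9 ± 2.76 CPM, a 444-fold difference with a 95% counting interval of 78.9 to 17618 because wild type held 1 read. Its neighbours NCU07150 and NCU07149 rose 151-fold, to 79.7 ± 4.35 CPM, and 36.7-fold, to 67.1 ± 11.1 CPM. On linkage group II, NCU09604, at 73202 to 74342, rose from 0.935 ± 0.155 to 31.8 ± 3.28 CPM (log2 change 5.09 ± 0.18, edgeR adjusted p = 3.62e-06). Far from any end, NCU00607, at 7857817 to 7858572 of linkage group I, fell 771-fold, from 517 ± 28.9 to 0.619 ± 0.876 CPM (edgeR adjusted p = 8.1e-06). Other large rises were those of NCU07249 (6.79 ± 0.52), NCU07147 (5.13 ± 0.64), NCU09634 (5.04 ± 0.43), NCU17064 (4.47 ± 0.24), NCU10037 (4.05 ± 0.63), NCU07148 (4.04 ± 0.73) and NCU09633 (5.25 ± 0.22), whose model overlaps another. NCU00370 had no wild-type read and stood at least 3.64-fold higher, a call that was lost without wild-type replicate 1, wild-type replicate 2 or Δset-7 replicate 1 (edgeR adjusted p = 0.0650, 0.0959 and 0.206). Other large falls were those of NCU08438 (-5.52 ± 0.31), NCU16445 (-5.22 ± 0.29), NCU00855 (-4.15 ± 0.12), NCU00322 (-4.13 ± 0.53), NCU04205 (-4.08 ± 0.28), NCU09964 (-3.80 ± 0.40), NCU06427 (-3.77 ± 0.28), NCU09424 (-3.54 ± 0.29) and NCU01957 (-4.15 ± 0.30). In all, 1894 of 8216 genes changed (23.1%), 950 up and 944 down, of which 82 rose and 84 fell at least 4-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The count fell when any 1 wild-type or Δset-7 library was left out. Such fits leave 1 library in a group and so have less power. The calls they shared with the main fit kept their sign. With library totals in place of TMM scaling the median of all genes shifted by 0.29, 3243 genes passed and 84.3% of them were up, against 50.2%. Where wild type or the mutant held few reads, 1 library also moved the size of a change. Without wild-type replicates 1 and 2 it was 10.20 and 6.15 for NCU07150, 10.50 and 5.63 for NCU07249. It was 10.04 and 3.95 for NCU07147, 6.96 and 4.07 for NCU09634, 6.72 and 2.99 for NCU10037, and 8.97 and 2.87 for NCU07148. Without Δset-7 replicates 1 and 2 it was -15.35 and -8.69 for NCU00607 and -3.52 and -5.14 for NCU00322, and without replicate 1 it was -6.27 for NCU08438 and -4.45 for NCU06427.

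Of 17 tested cell wall protein genes (acw and ncw symbols), 10 fell and 0 rose in Δset-7, 11 when adjusted over the list alone (limma camera adjusted p = 8.79e-07, and adjusted p = 0.471 with an estimated correlation). They include ncw-5, whose model overlaps another and which changed by -5.13 ± 0.17, from 5184 ± 477 to 148 ± 4.87 CPM, ncw-3 (-2.83 ± 0.18), acw-12 (-2.52 ± 0.17) and ncw-1 (-2.11 ± 0.18). Of 11 arginine biosynthesis genes, 6 rose and 1 fell, 8 and 1 when adjusted over the list alone (limma camera adjusted p = 0.000616, and adjusted p = 0.471 with an estimated correlation). The ornithine carbamoyltransferase gene arg-12 rose from 27.1 ± 0.498 to 65.7 ± 2.36 CPM and the argininosuccinate lyase gene arg-10 from 59.1 ± 0.214 to 140 ± 9.30 CPM, whereas arg-13, a mitochondrial carrier gene, fell from 39.7 ± 2.95 to 15.4 ± 3.50 CPM. Of 26 complex I genes, 11 rose and 0 fell, 13 when adjusted over the list alone, by a median of 0.26 (limma camera adjusted p = 3.26e-05, and adjusted p = 0.669 with an estimated correlation). An example is nuo51 (0.54 ± 0.10), whose call was lost without wild-type replicate 1 or 2 (edgeR adjusted p = 0.0501 and 0.0646). Of 9 clock-controlled genes (ccg symbols), 4 fell and 0 rose, also when adjusted over the list alone (limma camera adjusted p = 0.000161, and adjusted p = 0.277 with an estimated correlation), with ccg-13 at -2.34 ± 0.13 and ccg-14 at -2.01 ± 0.16. Of 11 genes of the clock, light response and carotenoids, 6 fell and 0 rose, also when adjusted over the list alone (limma camera adjusted p = 0.00490, and adjusted p = 0.669 with an estimated correlation). Among them, the phytoene desaturase gene al-1 fell from 1826 to 718 CPM (-1.35 ± 0.23). The core clock gene frq was at -0.80 ± 0.17, a call lost without wild-type replicate 1, wild-type replicate 2 or Δset-7 replicate 1 (edgeR adjusted p = 0.0579, 0.0764 and 0.0541). Of 10 conidiation genes, markers of asexual spores, 3 fell and 0 rose, 4 when adjusted over the list alone (limma camera adjusted p = 0.0496, but 0.0564 without wild-type replicate 2 and 0.0714 without Δset-7 replicate 1). Their adjusted p = 0.483 with an estimated correlation. Among them were the transcription factor genes csp-1 (-0.96 ± 0.15) and csp-2 (-0.97 ± 0.13). Histones (0 of 7 genes changed, 3 up when adjusted over the list alone, limma camera adjusted p = 0.0454), the proteasome (1 up of 17, 1 when adjusted over the list alone, 0.01) and the vacuolar ATPase (2 up of 14, 1 when adjusted over the list alone, 0.00680) also passed as lists, but at adjusted p = 0.670, 0.722 and 0.670 with an estimated correlation. With library totals 7 histone, 16 proteasome, 13 vacuolar ATPase and 24 complex I genes rose in Δset-7. The histone call was lost without wild-type replicate 1, Δset-7 replicate 1 or Δset-7 replicate 2 (limma camera adjusted p = 0.131, 0.0748 and 0.0880).

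Most tested genes changed in Δnpf against wild type. NCU04869, at 554456 to 555600 of linkage group IV, rose from 0.0373 ± 0.0528 to 437 ± 1.50 CPM, and NCU04867, close to it, from 0.0923 ± 0.0250 to 120 ± 10.8 CPM (1257-fold, with a 95% counting interval of 429 to 6099). NCU07152, at the right end of linkage group V, rose to 153 ± 5.51 CPM, and ncw-5 fell 163-fold, to 31.8 ± 2.45 CPM (edgeR adjusted p = 1.12e-07). NCU07033 fell from 529 ± 41.3 to 0.280 ± 0.212 CPM and NCU10865 fell 808-fold, from 391 ± 17.1 to 0.476 ± 0.0641 CPM (edgeR adjusted p = 1.12e-07). Other large rises were those of NCU00370 (at least 379-fold), NCU05472 (at least 269-fold), NCU10644, NCU10502, NCU06590, NCU07500, NCU07501, NCU05039 and NCU07150 (8.48 ± 0.44). Other large falls were those of NCU07034 (at least 177-fold), NCU00607 (-10.46 ± 0.46), NCU08052 (-9.03 ± 1.23), NCU08438, NCU00732 (-7.44 ± 0.55) and 4 genes whose models overlap others: NCU09968 (at least 773-fold), NCU09969 (at least 51.8-fold), NCU16445 and NCU05855. Genes with 1 to 3 reads in a group have wide 95% counting intervals: 2476 to 545025 for the rise of NCU04869, 871 to 191872 for NCU07152, 305 to 9143 for NCU06590, 216 to 47802 for NCU07500, 198 to 43757 for NCU10502, and 199 to 2837 for NCU10644. They are 103 to 3109 for NCU07501, and 124 to 3716 for NCU05039. As folds of decrease they are 378 to 83177 for NCU16445, 238 to 7099 for NCU05855 and 94.3 to 20831 for NCU08438. Without Δnpf replicate 2 the change was -11.85 for NCU07033 and -9.19 for NCU00732 (-6.75 without replicate 1), and without wild-type replicates 1 and 2 it was 11.44 and 7.38 for NCU07150. In all, 5939 of 8216 genes changed (72.3%), 3065 up and 2874 down, 740 and 617 of them at least 4-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With library totals the median of all genes moved from 0.02 to 0.39, and 68.1% of 5954 changed genes were up, against 51.6%. The mating-type gene matA-1, which only strains of mating type A carry, had no read in Δnpf (at least 14.6-fold lower). The gene mfa-1, for the pheromone precursor of mating type a, rose from 4.79 ± 0.228 to 99.7 ± 10.0 CPM. The labels state no mating type, and a difference in mating type was not separated from loss of npf.

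Of 18 mitochondrial import genes (tim and tom symbols), 17 rose and 0 fell in Δnpf, also when adjusted over the list alone (limma camera adjusted p = 1.35e-05, and adjusted p = 0.473 with an estimated correlation). The inner membrane translocase genes tim22, from 14.9 ± 1.18 to 140 ± 1.67 CPM, and tim54 (2.63 ± 0.15) are examples. All 10 heat shock genes (hsp symbols) rose, also when adjusted over the list alone (limma camera adjusted p = 0.00112, and adjusted p = 0.390 with an estimated correlation), with the mitochondrial chaperonin gene hsp60 going from 52.8 ± 9.30 to 512 ± 45.6 CPM and hsp70-5 at 2.38 ± 0.11. The 5 genes of the shorter heat shock list rose as well, also when adjusted over the list alone (limma camera adjusted p = 0.0227, and adjusted p = 0.390 with an estimated correlation). Of 17 proteasome genes, 14 rose and 0 fell, also when adjusted over the list alone (limma camera adjusted p = 0.00116, and adjusted p = 0.517 with an estimated correlation), among them rpt-3 (1.33 ± 0.11) and rpn-11 (1.23 ± 0.09). Of 7 histone genes, 5 rose and 0 fell, also when adjusted over the list alone (limma camera adjusted p = 0.0351, and adjusted p = 0.543 with an estimated correlation). The histone genes hH3 and hH4-1 went from 1475 ± 64.4 to 5719 ± 361 CPM and from 593 ± 7.96 to 2646 ± 90.7 CPM. Of 11 arginine biosynthesis genes, 9 rose and 2 fell, also when adjusted over the list alone (limma camera adjusted p = 0.0127, and adjusted p = 0.473 with an estimated correlation), including the carbamoyl phosphate synthetase subunit genes arg-2 (2.65 ± 0.13) and arg-3, from 47.0 ± 3.14 to 397 ± 4.03 CPM. Of 9 genes for cellulose and hemicellulose use, 7 fell and 1 rose, also when adjusted over the list alone (limma camera adjusted p = 0.0315, and adjusted p = 0.390 with an estimated correlation). The cellodextrin transporter gene cdt-1, whose model overlaps another, went from 384 ± 14.5 to 9.28 ± 0.416 CPM and the cellobiohydrolase gene cbh-1 was at -3.89 ± 0.19. Of 69 glycoside hydrolase genes (gh symbols), 31 fell and 14 rose, 31 and 13 when adjusted over the list alone (limma camera adjusted p = 0.0135, and adjusted p = 0.450 with an estimated correlation), with gh28-1 at -6.46 ± 0.33. With library totals 22 of them fell and 18 rose. Of 17 cell wall protein genes, 13 fell and 3 rose, also when adjusted over the list alone (limma camera adjusted p = 0.00112, and adjusted p = 0.483 with an estimated correlation). Of 9 clock-controlled genes, 8 fell and 0 rose, also when adjusted over the list alone (limma camera adjusted p = 0.00116, and adjusted p = 0.390 with an estimated correlation), with ccg-14 going from 46750.1 ± 1184 to 1049 ± 195 CPM. Of 11 clock, light and carotenoid genes, 7 fell and 2 rose, 8 and 2 when adjusted over the list alone (limma camera adjusted p = 0.0363, but 0.0561 without wild-type replicate 2, and adjusted p = 0.578 with an estimated correlation), including the photoreceptor gene vvd (-3.16 ± 0.17) and al-1 (-2.72 ± 0.24). Ribosomal protein genes (crp symbols), 5 up and 0 down of 7, also when adjusted over the list alone, passed at limma camera adjusted p = 0.0496, but not without wild-type replicate 1, wild-type replicate 2 or Δnpf replicate 1 (0.0635, 0.0701 and 0.102). Their adjusted p = 0.648 with an estimated correlation. Of the 10 conidiation genes 3 rose and 3 fell, also when adjusted over the list alone. Their median was -0.31 and their mean 0.41 (limma camera, down, adjusted p = 0.693), and the median was 0.06 with library totals. The hydrophobin gene eas rose from 143 ± 17.6 to 1325 ± 681 CPM and the transcription factor gene csp-1 fell (-2.09 ± 0.16), and without Δnpf replicate 1 the change of eas was 2.56.

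In Δset-7 Δdim-5 against wild type, large rises lay both near chromosome ends and inside linkage groups. The hydrophobin gene eas, which coats conidia, rose 116-fold, from 143 ± 17.6 to 16641 ± 9081 CPM (6.86 ± 0.62), and was at 6.15 without Δset-7 Δdim-5 replicate 1. NCU09734 on linkage group IV rose 333-fold, from 1.20 ± 0.639 to 421 ± 6.74 CPM (edgeR adjusted p = 5.34e-05), and was at 9.12 without wild-type replicate 2. NCU09604 rose 104-fold, to 96.9 ± 6.90 CPM, and NCU10009 fell 254-fold, from 74.0 ± 3.64 to 0.279 ± 0.0190 CPM (edgeR adjusted p = 4.64e-07 for each). Other large rises were those of NCU00848 (6.34 ± 0.46), NCU04282 (6.24 ± 0.34), NCU07149 (5.94 ± 0.21), NCU07150 (7.64 ± 0.44), NCU07249 (5.85 ± 0.55), NCU07147 (5.50 ± 0.63) and gh18-4, of a family that holds chitinases (6.21 ± 0.48). Those of NCU07152 and NCU06505 rest on 1 wild-type read each, with 95% counting intervals of 137 to 30406 and 271 to 60032. Other large falls were those of NCU00837 (at least 53.2-fold), NCU11053 (-6.85 ± 0.24), NCU09360 (-6.49 ± 0.33), NCU09425 (-5.90 ± 0.45), NCU04907 (-5.26 ± 0.17), NCU09429 (-5.26 ± 0.57). NCU02858 (-5.17 ± 0.28), NCU10059 (-4.90 ± 0.31), NCU11279 (-4.65 ± 0.30), NCU03816 (95% counting interval 34.0 to 7542, as a fold of decrease) and mig-6, whose model overlaps another (-5.03 ± 0.45), fell as well. Without wild-type replicates 1 and 2 the change was 10.60 and 6.55 for NCU07150, 9.56 and 4.69 for NCU07249 and 10.42 and 4.32 for NCU07147. It was 5.38 for gh18-4 and -5.53 for NCU10059 without Δset-7 Δdim-5 replicate 1, 8.59 for NCU06505 without the same library, and -5.94 for NCU02858 without replicate 2. In all, 2432 of 8216 genes changed (29.6%), 1169 up and 1263 down, 209 and 95 of them at least 4-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The count was 1155 without wild-type replicate 1 and 1363 without wild-type replicate 2. With library totals the median shifted by 0.21, and 74.6% of 2912 changed genes were up, against 48.1%.

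Of the 10 conidiation genes, 6 rose and 1 fell in Δset-7 Δdim-5, also when adjusted over the list alone (limma camera adjusted p = 0.0423, but 0.0550 without wild-type replicate 1, and adjusted p = 0.353 with an estimated correlation). They include the transcription factor gene fl, from 50.7 ± 2.74 to 212 ± 29.7 CPM, and acon-3, from 0.721 ± 0.0694 to 7.62 ± 1.06 CPM. The conidiation gene con-13 had 1 read in wild type and 174 in the mutant (95% counting interval of the fold 67.8 to 15203). Of 25 mutagen sensitivity and repair genes (mus and uvs symbols), 10 rose and 1 fell, 11 and 1 when adjusted over the list alone (limma camera adjusted p = 0.00793, but 0.0558 without Δset-7 Δdim-5 replicate 2, and adjusted p = 0.353 with an estimated correlation). Among them were mus-40 (1.13 ± 0.17) and the double-strand break repair gene mus-23 (0.96 ± 0.15). Of 6 curated DNA repair genes, 3 rose and 0 fell, 4 when adjusted over the list alone (limma camera adjusted p = 0.0423, but 0.0712 without wild-type replicate 1 and 0.155 without Δset-7 Δdim-5 replicate 2, and adjusted p = 0.353 with an estimated correlation). One of them, the Ku protein gene mus-51, was at 0.72 ± 0.15, a call lost without wild-type replicate 2 (edgeR adjusted p = 0.0651). Of 230 genes flanking the centromeres, 66 fell and 23 rose, 69 and 24 when adjusted over the list alone (limma camera adjusted p = 0.00871, and adjusted p = 0.353 with an estimated correlation), with a median of -0.19 that was 0.01 with library totals, where 49 fell and 38 rose. Of 9 clock-controlled genes, 5 fell and 1 rose, also when adjusted over the list alone (limma camera adjusted p = 0.0423, but 0.0550, 0.0704 and 0.0871 without wild-type replicate 1, wild-type replicate 2 and Δset-7 Δdim-5 replicate 2), with ccg-14 at -0.98 ± 0.16. Their adjusted p = 0.353 with an estimated correlation. Of 7 histone genes, 3 rose and 0 fell, 6 when adjusted over the list alone (limma camera adjusted p = 0.0373, but 0.0707 without wild-type replicate 1 and 0.101 without Δset-7 Δdim-5 replicate 2, and adjusted p = 0.581 with an estimated correlation). None of the 26 complex I genes or 7 ribosomal protein genes passed the edgeR test, overall or adjusted over the list alone, nor did these lists by limma camera (adjusted p = 0.907 for each). With library totals 6 complex I genes rose in Δset-7 Δdim-5.

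Δset-7 Δdim-5 and Δset-7 were also compared directly. In Δset-7 Δdim-5, NCU09734 rose from 1.22 ± 0.819 to 421 ± 6.74 CPM, eas from 99.4 ± 52.5 to 16641 ± 9081 CPM and NCU00607 from 0.619 ± 0.876 to 62.1 ± 11.1 CPM. By contrast, NCU04917 fell from 37.7 ± 0.166 to 0.339 ± 0.272 CPM and NCU10009 from 22.2 ± 0.0666 to 0.279 ± 0.0190 CPM. Without Δset-7 replicate 1 the change was 9.33 rather than 8.37 for NCU09734, 8.06 rather than 7.39 for eas (6.68 without Δset-7 Δdim-5 replicate 1) and 12.29 rather than 6.53 for NCU00607 (5.63 without replicate 2). Without Δset-7 Δdim-5 replicates 1 and 2 it was -6.12 and -7.90 rather than -6.71 for NCU04917. Of 17 cell wall genes 12 rose and 0 fell, 13 when adjusted over the list alone (limma camera adjusted p = 2.21e-06, and adjusted p = 0.343 with an estimated correlation). Of 10 conidiation genes 6 rose and 0 fell, 8 when adjusted over the list alone (limma camera adjusted p = 5.43e-05, and adjusted p = 0.278 with an estimated correlation). Of 11 clock and light genes 7 rose and 0 fell, also when adjusted over the list alone (limma camera adjusted p = 0.00387, and adjusted p = 0.451 with an estimated correlation). Of 11 arginine genes 8 fell (limma camera adjusted p = 5.43e-05, and adjusted p = 0.292 with an estimated correlation). Of 26 complex I genes 8 fell (limma camera adjusted p = 7.02e-05, and adjusted p = 0.451 with an estimated correlation). Of 10 heat shock genes 6 fell (limma camera adjusted p = 0.00180, and adjusted p = 0.278 with an estimated correlation). Of 230 centromere-flanking genes 69 fell and 32 rose (limma camera adjusted p = 0.00862, and adjusted p = 0.297 with an estimated correlation). The counts of arginine, complex I and heat shock genes were equal when adjusted over the list alone, and those at the centromeres were 69 and 34. In all, 2625 genes differed, 1297 up and 1328 down, and 1499 without Δset-7 Δdim-5 replicate 1 (edgeR).

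Compared directly with Δset-7, Δnpf had 17 of 18 mitochondrial import genes higher (limma camera adjusted p = 1.20e-06, and adjusted p = 0.522 with an estimated correlation) and 8 of 10 heat shock genes higher (0.00247, and adjusted p = 0.394 with an estimated correlation). It had 13 of 14 vacuolar ATPase genes, 16 of 26 complex I genes and 36 of 69 glycoside hydrolase genes lower (limma camera adjusted p = 0.00247, 0.00247 and 0.00260). For these 3 lists adjusted p = 0.600, 0.600 and 0.394 with an estimated correlation. Only 1 complex I gene and 10 glycoside hydrolase genes went the other way, and all these counts were equal when adjusted over the list alone. NCU04869 was at least 2422-fold higher and NCU04867 at least 666-fold higher in Δnpf, and NCU10865 fell from 206 ± 24.6 to 0.476 ± 0.0641 CPM. In all, 5557 genes differed, 2858 up and 2699 down (edgeR). In Δset-7 Δdim-5 against Δnpf all 18 mitochondrial import genes were lower (limma camera adjusted p = 5.03e-06), 9 of 10 heat shock genes were lower (0.000330) and 15 of 17 proteasome genes were lower (0.00124). For these 3 lists adjusted p = 0.446, 0.323 and 0.601 with an estimated correlation. By contrast, 13 of 17 cell wall genes were higher and 2 lower (limma camera adjusted p = 0.000766, and adjusted p = 0.534 with an estimated correlation), again with the same counts when adjusted over the list alone. NCU07033 was at 137 ± 33.3 against 0.280 ± 0.212 CPM (8.80, and 9.91 without Δnpf replicate 2), and NCU07212 was at least 130-fold lower. In all, 5936 genes differed, 2931 up and 3005 down (edgeR), and library totals moved the median by -0.16.

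Genes near chromosome ends, where facultative heterochromatin of this fungus mostly lies, rose more often than other genes in all 3 mutants. Within 100 kb of an end, 95 of 292 genes rose in Δset-7 (32.5%, against 10.8% elsewhere; odds ratio 3.99, 95% interval 3.05 to 5.17, Fisher's exact test, two-sided, p = 1.96e-22). In Δset-7 Δdim-5, 112 rose (38.4% against 13.3%; odds ratio 4.04, 3.13 to 5.19, Fisher's exact p = 1.87e-25), and in Δnpf 146 (odds ratio 1.71, 1.35 to 2.18, p = 8.21e-06). In Δset-7 the share fell with distance, from 36.4% of genes within 50 kb to 9.33% beyond 800 kb, and at the right end of linkage group V 18 of 30 genes rose, 9 of them at least 4-fold. At the left end of linkage group II, 12 of 31 rose, 6 of them at least 4-fold. Falls were rarer near ends, with odds ratios of 0.379 in Δset-7 (Fisher's exact p = 7.71e-05), 0.598 in Δnpf (p = 0.000132) and 0.483 in Δset-7 Δdim-5 (p = 0.000265). These calls were lost for 4-fold falls in Δset-7 and Δset-7 Δdim-5 (Fisher's exact p = 0.373 and 0.776) and with library totals in Δnpf (p = 0.0565). Rises of at least 4-fold had odds ratios of 13.7 in Δset-7 (95% interval 8.13 to 22.6), 2.51 in Δnpf and 6.30 in Δset-7 Δdim-5. Between mutants, rises in Δset-7 Δdim-5 against Δset-7 had an odds ratio of 1.40 near ends (Fisher's exact p = 0.0271) and rises in Δnpf against Δset-7 one of 1.09 (p = 0.492). As lists, the ends passed limma camera in Δset-7 (105 up and 20 down when adjusted over the list alone, adjusted p = 8.79e-07), Δset-7 Δdim-5 (118 and 29, 1.06e-05) and Δnpf (146 and 72, 0.0363, but 0.0669 without wild-type replicate 2). With an estimated correlation their adjusted p was 0.277, 0.353 and 0.483. The chromosome interiors, with 826 genes up and 896 down in Δset-7 (820 and 888 when adjusted over the list alone), had a median of -0.01 that was 0.28 with library totals, and their camera call (adjusted p = 0.00465) held at 0.0390 with an estimated correlation. They hold 7694 of the 8216 tested genes. Their test thus sets them against the ends and centromere flanks and is no separate evidence. The odds ratio of rises in Δset-7 was 7.15 without wild-type replicate 1, 7.77 without wild-type replicate 2 and 2.35 with library totals. That in Δset-7 Δdim-5 was 6.11 without wild-type replicate 1. Those of falls were 0.117 in Δset-7 without wild-type replicate 1 and 0.778 (Fisher's exact p = 0.299) in Δset-7 Δdim-5 without wild-type replicate 2. Genes are not independent replicates, and the Fisher's exact p-values printed here are unadjusted. Adjusted together over the 12 tests near ends, that of rises in Δset-7 Δdim-5 against Δset-7 became 0.0465.

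**Figure D1:**
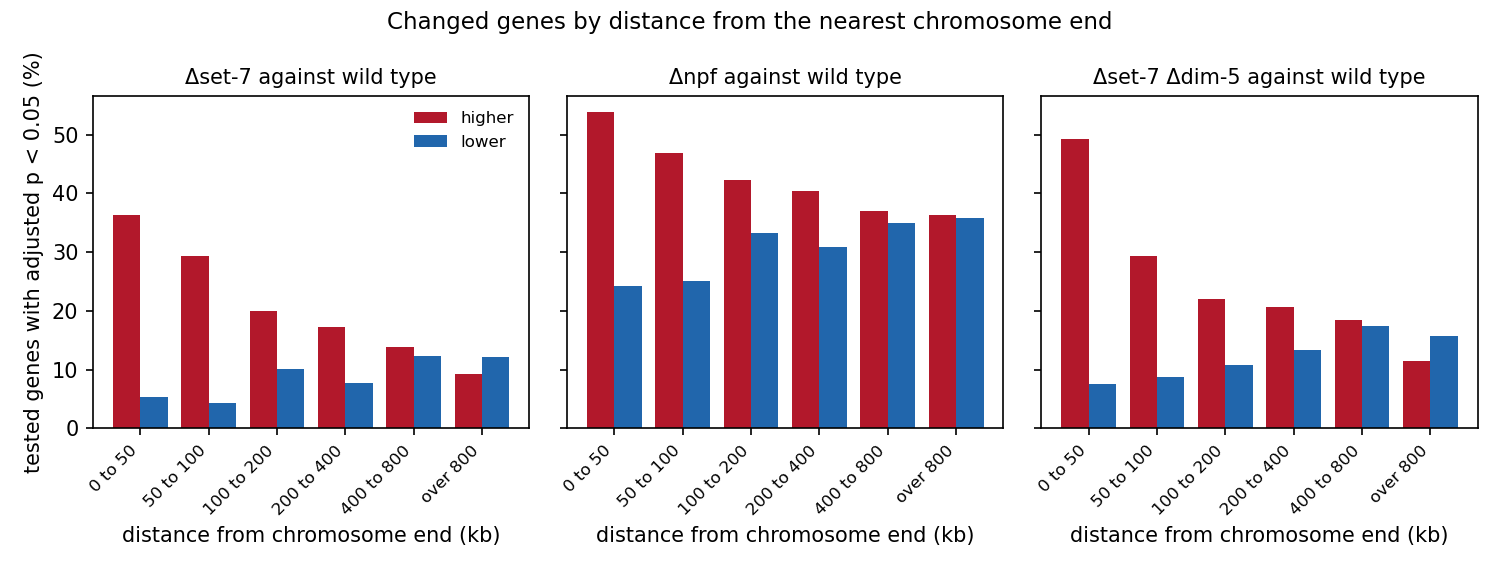
Percent of tested genes that rose in each mutant against wild type, by distance of the gene midpoint from the nearest chromosome end in kb. In Δset-7 the share is 36.4% within 50 kb and 9.33% beyond 800 kb.

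The mutants shared many changed genes. At a 4-fold change or more, 37 genes rose and 13 fell in all 3 mutants, and 15 of the rises and 0 of the falls lay within 100 kb of an end. The shared rises include NCU07147, NCU07148, NCU07149, NCU07150 and NCU07152 on linkage group V and NCU09604, NCU09633 and NCU09634 on linkage group II, and the shared falls include NCU00607, gh28-1 and NCU00732. Δset-7 and Δnpf shared 595 rises and 715 falls, where n1×n2/N gives 354 and 330. Δset-7 and Δset-7 Δdim-5 shared 364 rises and 395 falls, against 135 and 145, and Δnpf and Δset-7 Δdim-5 shared 542 and 684, against 436 and 442. In 20 simulations of unchanged groups that share the wild-type libraries, at most 1 gene was shared in a direction. Unchanged groups give few calls to share, so this count cannot show how much overlap the shared libraries add. The covariance of fold changes was 0.495, 0.347 and 0.452 for the 3 pairs, and at most 0.0254 in the simulations. Covariance grows with the size of the changes, and the simulated groups hold none beyond noise. This difference therefore does not measure agreement between mutants. The correlation was 0.346, 0.443 and 0.262, against 0.420, 0.418 and 0.423 in the simulations. The simulated values reflect noise alone, so a correlation above or below them does not measure agreement between mutants either. Part of the excess of shared genes over n1×n2/N may come from the shared wild-type libraries. Fits without wild-type replicate 1 or 2 gave smaller overlaps. They call fewer genes and still share the wild-type library that remains, so they cannot show how much the sharing adds. The submitters' own lists of 4-fold changes name 151, 1343 and 242 genes for Δset-7, Δnpf and Δset-7 Δdim-5. Of these, 150, 1283 and 240 were tested here, all with the same sign, and 145, 1230 and 236 passed at least 4-fold (r = 0.996, 0.994 and 0.995 across genes). These lists were made from the same libraries and are no independent evidence.

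The Δdim-5 sample, germinated conidia, holds transcripts where dim-5 alone is missing, but in another cell state than the mycelia of wild type, and as 1 listed sample, so that its values were compared without a test as planned. The labels give growth at 32 °C for 16 h for this sample and state neither temperature nor time for the wild-type RNA libraries. Growth conditions may thus differ too. The names of its 2 count files call them replicates 1 and 2, with different barcodes and strain numbers. These files may therefore be 2 libraries of 2 strains. NCU09635, 4.92 kb from the left end of linkage group IV, stood at 3805 and 16028 CPM in the 2 files, against 18.7 ± 2.00 CPM in wild type. Its neighbour pks-5, a polyketide synthase gene whose model overlaps another, stood at 774 and 2997 CPM, against 3.88 ± 0.654 CPM. NCU07029 (344 and 321 CPM against 0.558 ± 0.127), NCU09167 (362 and 624 against 0.877 ± 0.777), NCU09168 (239 and 500 against 0.520 ± 0.272) and NCU10285 (338 and 767 against 1.50 ± 0.534) were higher too. NCU09775 (9.17 and 0 CPM against 958 ± 30.0), NCU08052 (9.30 and 0.254 against 824 ± 101) and con-8 (27.5 and 1.52 against 2246 ± 238) were lower, and NCU09968 had no read. Of 7073 genes with at least 5 CPM, 648 were at least 4-fold higher and 237 at least 4-fold lower in both files, while the median gene was higher by 0.77, or by 0.08 with TMM scaling. The balance of directions rests on the scaling: in Δdim-5 against wild type with TMM factors, 279 genes were at least 4-fold higher and 446 at least 4-fold lower. With the 2 files taken as 2 libraries, as their names read, edgeR called 2680 rises and 2562 falls in Δdim-5, 547 and 736 of them at least 4-fold. Against 10000 random lists, the medians of mitochondrial import (1.62), heat shock (1.65), proteasome (1.45) and chromosome-end genes (0.98) lay at percentiles 99.89, 99.77, 99.7 and 99.53, and those of centromere flanks (0.12), clock and light (-1.44), conidiation (-1.46) and ccg genes (-2.06) at 0, 0.05, 0.23 and 0.28. The 2 files correlated at r = 0.926 on log2 CPM, and file 2 alone gave 1357 4-fold genes in place of 885.

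Hi-C compared how chromosome ends meet in the nucleus, with 1 balanced matrix per strain and so with no replicate error and no test. Contact between ends of different linkage groups was 3.36 times the matrix mean in wild type, 2.16 in Δset-7, 2.31 in Δnpf and 1.87 in Δset-7 Δdim-5, ratios to wild type of 0.642, 0.686 and 0.556. Of 84 pairs of ends, 75, 79 and 78 lay below wild type. Contact between the left and right ends of a linkage group, over the mean at the same distance, was 10.8 in wild type and 4.76, 6.73 and 3.68 in the mutants, where linkage group I has no distance-matched pairs. Exceptions were linkage group V, where the wild-type value of 1.35 stood against 1.46 in Δset-7 and 1.60 in Δnpf, and linkage group VI in Δnpf, with a ratio of 1.03. The left end of linkage group V, the arm that carries the ribosomal RNA gene repeats, had little contact with other ends in wild type (0.923) and a ratio of 0.979 in Δset-7, whereas the ratio at the other 13 ends lay between 0.600 and 0.753. In Δset-7 the smallest ratios belonged to the right end of III with the left end of VII (0.370), the left end of IV with the right end of VI (0.456) and the right end of II with the left end of VI (0.470). The largest belonged to the left end of V with the left ends of VII (1.45), VI (1.26) and IV (1.16). In Δnpf the smallest were VI right with VII right (0.357), I left with II left (0.365) and III right with VII right (0.396), and the largest II left with IV right (1.24), I right with VII left (1.20) and IV left with V left (1.18). In Δset-7 Δdim-5 the smallest were III right with VI right (0.283), I right with VII right (0.375) and I right with III right (0.381), and the largest V left with VI left (1.29), III right with V left (1.26) and II right with V left (1.20). The wild-type matrix was recomputed from an earlier experiment, so that experiment and mutation cannot be told apart. With ends of 50 kb the left-right ratio was 0.380 in Δnpf and 0.226 in Δset-7 Δdim-5, in place of 0.624 and 0.341.

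Contacts among centromeres differed less between strains than those among ends. Centromere contact between linkage groups was 5.46 times the matrix mean in wild type, 5.04 in Δset-7, 5.18 in Δnpf and 4.76 in Δset-7 Δdim-5 (ratios 0.922, 0.948 and 0.872). As medians over bin pairs divided by the matrix median, these ratios were 0.694, 0.758 and 0.543, and those between ends 0.459, 0.572 and 0.385. On the observed over expected matrices they were 0.669, 0.726 and 0.598, and those between ends 0.470, 0.539 and 0.387. Over the mean between linkage groups they were 0.715, 0.814 and 0.635, and those between ends 0.497, 0.5885 and 0.405. Contact between centromeres and ends was 0.400 in wild type and 0.544, 0.450 and 0.628 in the mutants, ratios of 1.36, 1.13 and 1.57. These were 0.973 in Δset-7 and 0.950 in Δnpf on the observed over expected matrices, and 0.966 in Δnpf over the mean between linkage groups. The share of contacts between linkage groups was 47.3% in wild type, 61.1% in Δset-7, 55.2% in Δnpf and 65.0% in Δset-7 Δdim-5. Contact fell with distance along a linkage group with a log-log slope of -1.17 in wild type, -0.99 in Δset-7, -1.05 in Δnpf and -0.92 in Δset-7 Δdim-5 from 50 kb to 1 Mb. Across bin pairs, which are not replicates, Spearman's rho with wild type was 0.880, 0.848 and 0.856 within linkage groups and 0.508, 0.424 and 0.454 between them. The matrices sum to 12851236, 10590940, 4661063 and 10116833, and their read depths were not stated.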

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

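The tests of batch, background contacts, read length, expression level, gene length and thinning were chosen after the main results were seen. For the last 3, what they would show was written down before they were run. Opposite changes were looked for in every pair of mutants. In Δset-7 and Δnpf, 222 genes changed in opposite directions, 7 of them at least 4-fold both ways, such as NCU08739 (2.47 and -5.07) and NCU01033 (-2.92 and 3.05). In Δset-7 and Δset-7 Δdim-5 there were 134, and 2 at least 4-fold: NCU04917 (2.69 and -4.02) and NCU03861 (-2.27 and 3.76). In Δnpf and Δset-7 Δdim-5 there were 608, and 7 at least 4-fold, such as NCU00850 (-3.62 and 3.85). For these pairs n1×n2/N gives 684, 280 and 880 opposite changes, and 13.7, 3.08 and 24.3 at least 4-fold. Opposite changes were thus rarer than independent lists would give. The shared wild-type libraries also push changes the same way, so this does not measure agreement between mutants. Of 10 conidiation genes, 3 fell and 0 rose in Δset-7 and 6 rose and 1 fell in Δset-7 Δdim-5, with limma camera adjusted p = 0.0496 and 0.0423, and adjusted p = 0.483 and 0.353 with an estimated correlation. Their median log2 difference between these mutants was 2.07 (limma camera adjusted p = 5.43e-05, and adjusted p = 0.278 with an estimated correlation).

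Genes near chromosome ends rose more often than other genes in Δset-7. Low expression or short genes near ends could produce such an excess. The exact common odds ratio was 4.23 over strata of mean expression in the 8 libraries (lower 95% bound 3.23). Over strata of gene length it was 3.93 (3.00), so gene length alone does not account for the excess. Mean expression includes the mutant libraries, in which these genes rose. Low expression in wild type was not tested and stays open. The wild-type batch is an open explanation: of the end genes that rose, 49.5% rose in both other mutants too, as a difference in the shared wild-type libraries would also give, so that batch and loss of set-7 cannot be told apart here.

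Most genes changed in Δnpf. A difference of the wild-type libraries alone would not carry over to Δset-7, against which 5557 genes still changed. Greater depth of wild type could add calls, but 5697 genes changed with wild-type counts thinned to the depth of the mutants. A difference in mating type may contribute, as matA-1 had no read and mfa-1 rose in Δnpf, and stays open. A difference in growth or library preparation specific to the Δnpf cultures, whose names give 1 strain number, may also contribute and was not tested.

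Contact between chromosome ends was lower in all 3 mutants. A uniform background of random contacts may lower it, but as the whole cause it would have to make up 50.9%, 44.7% and 63.3% of contacts for the ends and only 9.48%, 6.31% and 15.7% for the centromeres in Δset-7, Δnpf and Δset-7 Δdim-5. As medians over bin pairs divided by the matrix mean these were 54.2%, 44.8% and 64.1% for the ends and 5.17%, 9.34% and 24.5% for the centromeres. Divided by the matrix median they were 48.8%, 35.2% and 59.1% and 20.8%, 15.7% and 34.3%. A smaller background as part of the loss stays open. The share of contacts between linkage groups would need a background of 37.2%, 21.2% and 47.7%. Contact over the matrix mean at 50 kb within linkage groups was lower too, at 0.589, 0.715 and 0.477 of wild type. At 1 Mb these ratios were 0.948, 1.10 and 0.945. A loss particular to chromosome ends was therefore not shown. A ratio of 0.686 remained in Δnpf, whose name carries the same read length as wild type, and read length stays open for the other mutants. The wild-type matrix comes from an earlier experiment, so that experiment and mutation cannot be told apart.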

How the results depend on the processing

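Of 408 printed results with 4064 alternative values, 3722 values kept the call, 296 lost it, 42 moved and 4 reversed. Alternatives for library totals without TMM, thinning, contact over the mean between linkage groups, Hi-C without the left end of V, and background shares as medians or with bins of 40 kb were chosen after seeing the main results. The cause of these changes was not tested. Named genes lost 292 of 3794 calls in 88 results, 219 of them with 1 library left out, and cul-4 in Δnpf went to 0.0567 with library totals. The 4-fold counts were 166, 1357 and 304 for Δset-7, Δnpf and Δset-7 Δdim-5 against wild type, 253 for Δset-7 Δdim-5 against Δset-7, 1091 for Δnpf against Δset-7 and 1376 for Δset-7 Δdim-5 against Δnpf. Library totals gave 3243 genes in Δset-7. With 1 library left out, counts ran from 682 to 1598 in Δset-7, 1155 to 1818 in Δset-7 Δdim-5 and 1499 to 2313 between these mutants, where the lone library is assumed to vary like the other groups. Sample numbers do not pair samples (r from -0.157 to 0.109), and a replicate block gave 1729 genes in Δset-7. Lists called were 1, 0 and 0 with an estimated correlation, 21 in Δnpf and 11 in Δset-7 Δdim-5 with fry, and 3 to 10 in Δset-7 Δdim-5 with 1 library left out. Odds ratios of falls near ends were 0.325 in Δset-7 (Fisher's exact p = 0.373) and 0.581 in Δset-7 Δdim-5 (p = 0.776) for 4-fold changes and 0.747 in Δnpf with library totals (p = 0.0565), calls that were lost, and 0.426 to 0.778 in Δset-7 Δdim-5 with 1 library left out. Shared 4-fold rises and falls were 50 and 54 (Δset-7 and Δnpf), 54 and 16 (Δset-7 and Δset-7 Δdim-5) and 109 and 36 (Δnpf and Δset-7 Δdim-5). With 1 wild-type library left out, overlaps ran from 204 to 272 and 265 to 366, 157 to 169 and 139 to 155, and 276 to 290 and 366 to 383. File 2 alone gave 1357 genes in Δdim-5, and other choices as few as 725. Centromere-end contact reversed to 0.973 in Δset-7 and 0.950 in Δnpf on observed over expected matrices and to 0.966 in Δnpf over the mean between linkage groups. Left-right contact moved to 0.380 in Δnpf and 0.226 in Δset-7 Δdim-5 with ends of 50 kb, and centromere contact to 0.543 in Δset-7 Δdim-5 as a median divided by the matrix median. Contact between ends ranged from 0.459 to 0.723, 0.539 to 0.749 and 0.385 to 0.659 in the 3 mutants.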

Other observations

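The correlations between contact and expression by end were chosen after the main results were seen, and what they would show was written down before they were run. Over 14 chromosome ends, contact ratio and share of genes that rose had Spearman's rho of -0.323 in Δset-7 (permutation p = 0.259), 0.112 in Δnpf (p = 0.703) and -0.626 in Δset-7 Δdim-5 (p = 0.0190, Benjamini-Hochberg adjusted p = 0.0569). Pearson's r in Δset-7 Δdim-5 was -0.628 (permutation p = 0.00370, adjusted 0.0111), but -0.283 (p = 0.370) without 2 ends, so that a link between contact and expression by end may rest on single ends and cannot be told apart from chance here.

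RNA silencing genes moved both ways in Δnpf, 4 up and 2 down of 8, also when adjusted over the list alone (limma camera adjusted p = 0.819). The Dicer gene dcl-1 fell from 135 to 38.2 CPM, while qde-1, an RNA-dependent RNA polymerase gene, rose (1.21 ± 0.14). Of 12 constitutive heterochromatin genes, 3 rose and 1 fell in Δnpf (limma camera adjusted p = 0.490), with hpo, the gene of heterochromatin protein HP1, going from 26.3 to 73.2 CPM. Of 4 components of the PRC2 complex, 3 rose and 0 fell (0.199), where npf itself, which fell 20.0-fold in Δnpf, is not in the list because the reference names it cac-3. Of 5 mating genes 1 rose and 2 fell (0.936), of 20 peroxin genes 8 rose and 8 fell (0.778), and of 50 kinase genes 12 rose and 18 fell (0.419). With library totals 11 peroxin genes rose and 5 fell, and 18 kinase genes rose and 9 fell, so that the balance rests on the scaling. Of 6 polyketide synthase genes, 2 rose and 3 fell in Δnpf (0.819), with pks-3 going from 4.18 to 128 CPM, and 2 rose and 1 fell with library totals. Of 4 genes with con symbols 1 rose and 1 fell (limma camera adjusted p = 0.908). None of these lists passed the test in any mutant.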
